A study of Mus musculus with 10 samples.

How the data were processed

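Total RNA of 10 mouse tumours was hybridised to a mouse Affymetrix expression array of 1 colour, 1 array per tumour. Per the labels' protocols, the tumours grew under the skin of nude mice, and biotin-labelled cRNA was made from total RNA. The deposited values are linear probe set intensities made with MAS5, per the submitters' processing notes. The MAS5 version, its scaling target and its background settings are not given in the sources used here, and detection calls were not used here. The human tumour data that the design text names for comparison were not analysed here.

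The table held 45101 probe sets, of which 64 were controls. In the platform annotation 34958 probe sets carried 1 gene symbol, 932 carried several and named no gene, and 9160 were unnamed here. Of the 18193 genes, 18033 were matched by identifier to a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. No genome build is named for the array, so no coordinates are given. The probe set of highest mean signal stood for each gene.

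The design written before the data were examined took the deposited values as already scaled between arrays. The values contradicted this. The 2% trimmed mean of an array ran from 30.5 to 119.7 signal units, a ratio of 3.93, while the mean of the spiked-in hybridisation controls differed by a ratio of 1.29 at most. The log2(signal + 16) values were therefore quantile normalized between arrays. Quantile normalization had been listed beforehand as an alternative, and the values as deposited became the alternative in its place. This switch was made after the data had been seen and it changes several results, which are given both ways.

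The background level of an array was the 95th percentile of its signals over 83 probe sets for olfactory, vomeronasal and taste receptors, so about 5% of these lie above it by construction. A gene was above background in a tumour when its signal exceeded that level, and the 11931 genes above background in at least 3 tumours entered the tests. The number of arrays limits the precision. The labels give no condition other than tumour and no batch, so no groups were compared and no value within a batch could be had. In the sample order of the series, tumours 7, 23 and 16 come last, out of numeric order. They had the lowest mean log2 ratios of 3' to 5' control probe sets (0.63, 0.31 and 0.27, against 0.73 to 1.24 in the others). Whether their arrays were run apart is not given and was not tested. All 10 source labels carry the number 4 although the titles give 10 different numbers, and the titles were used. The labels do not say whether the tumours came from separate cultures or mice. The p-values of correlations between scores or array measures therefore rest only on the spread between these samples, part of which may be technical. Those for gene lists compare a list with random lists of genes in the same tumours and measure no spread between samples. Those of the variance test compare a gene with the other genes.

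Variation of single genes was tested with limma 3.58.1 in R 4.3.3, each gene's variance being set against a robust prior trended on mean level (1-sided F test, Benjamini-Hochberg adjusted, threshold 0.05). For 25 gene lists fixed beforehand, the median SD of the members was ranked among 10000 random lists of equal size matched on mean level in 20 bins (2-sided). The mean pairwise Pearson correlation of the members was ranked likewise (1-sided, higher). Mast cell and sex-linked genes had under 5 usable members and were not tested. Genes of a list are correlated, so the p-values for median SD are too small. A list score was the mean over members of the centred log2 value divided by the gene's SD. Scores were correlated over 229 pairs of lists with a 2-sided permutation test of 100000 resamples, leaving genes of both lists out of each, and exact permutation tests were used where 2 tumours were left out. The RNA quality measure was the mean log2 ratio of 3' to 5' control probe sets of Gapdh and Actb, and brightness was the log2 trimmed mean. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

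The steps were tested on simulated data. Among 11931 simulated genes the variance test recovered 0% of 100 genes with a 3-fold SD and 1% of 100 genes with a 5-fold SD, so it has almost no power here. The test of list variation called 100% of 20 lists of doubled SD and 5% of 20 unchanged lists. The test of co-variation called 100% of 20 correlated lists and 0% of 20 unrelated lists. The lists of doubled SD and the correlated lists were the same 20, with both changes at once. Unchanged lists were randomly drawn genes with independent values. Their rates therefore do not give the rate of false calls for lists whose genes are correlated. A correlation of 10 values had an unadjusted permutation p under 0.05 in 98% of 200 cases at a true r of 0.9. At a true r of 0 it did in 5% of 200 cases. Power after adjustment over 229 pairs was not simulated and is lower. The comparison of 2 probe sets of a gene, added after the data were seen, called 93% of 200 genes at a true r of 0.9 and 0.75% of 800 unrelated ones.

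The genes named follow a rule fixed beforehand. It takes a fixed set of Ewing sarcoma, lineage and sex-linked genes, the 20 genes of largest SD among those passing the variance test (0 passed), the 2 members of largest and the 2 of smallest SD in each list among those above background in at least 3 tumours, and members above background in no tumour. Any other gene named was chosen after its values were seen. Runx2, Trp53 and Ddx3y were not analysed here. Alternatives fixed beforehand were the mean of all probe sets of a gene, pseudocounts of 1 and 64, no filter, genes above background in all 10 tumours, leaving out each tumour, a prior without robustness or trend, other background levels, other choices of probe set, scores as medians, and scores with the 3'/5' ratio or the cell cycle score regressed out. Chosen after the data were seen were trimmed mean scaling, removal of brightness and the 3'/5' ratio from each gene, leaving out the 3 dimmest arrays, leaving matrix genes out of the repressed list, and the comparison of 2 probe sets.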

Results

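Gene expression was measured in 10 mouse tumours, numbered 4, 7, 8, 12, 14, 15, 16, 17, 23 and 28. They arose after EWS-FLI1, the fusion gene of human Ewing sarcoma, was introduced into murine FZ cells and the cells were transplanted into nude mice. There was no control sample, so the question the design allows is which genes the tumours share and which differ from tumour to tumour. Levels are quantile normalized log2(signal + 16) values from MAS5 signals, given as mean ± SD with n = 10 tumours. Arrays differed in brightness, with trimmed mean signals from 30.5 in tumour 17 to 119.7 in tumour 16. The number of genes above background ran from 9144 in tumour 8 to 12078 in tumour 16 and followed brightness (r = 0.945, permutation p = 0.00018, adjusted p = 0.00054 over 3 array measures, rho = 0.891, permutation p = 0.0011, and r = 0.918 without the 2 farthest tumours).

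**Figure D1:**
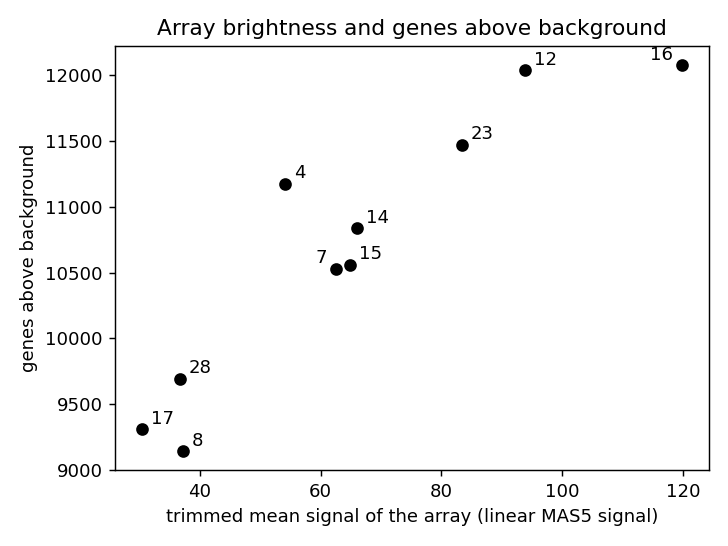
Each point is 1 tumour, labelled by its number, with the trimmed mean of its linear array signals on the x axis and its number of genes above background on the y axis. Tumour 17, the dimmest at 30.5, had 9310 genes above background and tumour 16, the brightest at 119.7, had 12078.

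Many genes known to be raised by EWS-FLI1 in human Ewing sarcoma were above background in every tumour. These included the histone methyltransferase gene Ezh2 (9.12 ± 0.20, SD, n = 10), the cyclin gene Ccnd1 (9.33 ± 0.90), Id2 (7.77 ± 0.54), Igf1 (8.16 ± 0.84), Cav1 (7.17 ± 0.68), Bcl11b (6.52 ± 0.83) and Myc (8.69 ± 0.30). Nkx2-2, a transcription factor gene used in Ewing sarcoma diagnosis, was above background in 4 of 10 tumours, with its highest values in tumours 8 (7.15), 7 (6.76) and 16 (5.86). Of the 42 measured genes of the activated list, 23 were above background in all tumours and 5 in none, namely Nr0b1, Kcnab3, Lipi, Npy1r and Cck. Dkk2 was above background in 4 tumours, Prkcb in 9, and Gli1 and Igf1r in 8 each.

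Genes known to be lowered by EWS-FLI1 in human cells were also widely detected, 24 of 28 in all tumours. Among them were the TGF-beta receptor gene Tgfbr2 (8.02 ± 0.54), Igfbp3 (8.86 ± 0.65) and the cell cycle inhibitor gene Cdkn1a (7.87 ± 0.72). The tumours grew in nude mice, so mouse host cells may add to the signals of the activated and repressed lists. These counts therefore do not show which cells used the genes. Of the diagnostic and neural markers, 8 of 25 were above background in all tumours and 5 in none, namely Nefl, Nefm, Nefh, S100b and Dcx. Cd99 (7.41 ± 0.56), Fli1 (5.90 ± 0.48) and Ewsr1 (9.93 ± 0.27) were above background in 10 of 10 tumours and Erg in 3. Whether the Fli1 and Ewsr1 probe sets report the introduced fusion was not tested.

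None of the 21 measured cartilage genes was above background in all tumours and 7 were in no tumour, among them Col2a1, the main cartilage collagen gene. Of the 34 joint progenitor genes, 6 were above background in all tumours, 19 in at least 3 and 8 in none. The joint gene Gdf5 was above background in 0 tumours, Prg4 in 6 and the chondrogenic regulator gene Sox9 in 5. Of the limb patterning genes, Hoxa9 (7.56 ± 1.27) was above background in 10 tumours, Hoxa10 (6.82 ± 1.16) in 9, and Hoxd10, Hoxd11, Hoxd12 and Hoxd13 in 0. Second probe sets of Hoxa9 and Hoxa10 had smaller SDs, of 0.66 and 0.30. Cell cycle genes were above background in all tumours for 30 of 31 members, and the proliferation marker Mki67 was at 9.32 ± 0.42. The tumour suppressor gene Cdkn2a (6.68 ± 1.05) was above background in 10 tumours. Over all genes, 7708 of 18193 were above background in 10 tumours and 4368 in 0. With the background at the 99th percentile of the receptor probe sets the former count was 4728.

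Skeletal muscle genes had the largest median SD of the lists tested. The fast myosin genes Myh4 (7.24 ± 2.78) and Myh1 (7.78 ± 2.66) were at 12.72 and 12.40 in tumour 12, and at 4.08 and 4.27 in tumour 16. The median SD of the 25 muscle genes was 1.96 against 0.33 in matched random lists (adjusted p = 0.000767, from an unadjusted p of 0.0002, the smallest the random lists can give). Fat cell genes had a median SD of 1.11 with the same adjusted p, and without tumour 23 it was 0.50 (adjusted p = 0.0441). Their most variable members were Car3 (9.03 ± 2.25) and the adiponectin gene Adipoq (5.58 ± 1.76), which was at 10.33 in tumour 23 and at most 5.68 in the others.

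Fibroblast and matrix genes had a median SD of 0.78 (adjusted p = 0.000767), with the matrix genes Postn (8.57 ± 1.10) and Fbln2 (6.64 ± 1.06) lowest in tumour 7 at 6.98 and 5.25. Macrophage and myeloid genes had a median SD of 0.57 (adjusted p = 0.000767), led by the neutrophil genes S100a8 (7.75 ± 1.93) and S100a9 (6.99 ± 1.92), at 11.57 and 10.81 in tumour 4. EWS-FLI1 repressed genes had a median SD of 0.66 (adjusted p = 0.000767), with Slit2 (7.64 ± 1.43) and Col3a1 (10.82 ± 0.96) varying most. In the activated list (median SD 0.44, adjusted p = 0.00637), Nkx2-2 (5.22 ± 1.02) and Pappa (6.08 ± 0.94) varied most and Ezh2 and Cdc25a (7.40 ± 0.19) least among members above background in at least 3 tumours. Second probe sets had SDs of 0.38 for Pappa and 0.68 for Slit2, but 1.05 for Col3a1, so a gene's spread can depend on the probe set.

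In all, 18 of 23 tested lists varied more than matched random lists and 0 varied less, while with the mean of all probe sets housekeeping genes varied less (median SD 0.18, adjusted p = 0.0360). The median SD was 0.70 for bone formation, 0.68 for cartilage, 0.67 for skin epithelium, 0.66 for lymphocytes and natural killer cells, 0.55 for joint progenitors, 0.51 for interferon response, 0.51 for endothelium, 0.48 for diagnostic and neural markers, 0.47 for IGF signalling, 0.46 for Wnt and Hedgehog, 0.45 for the p53 pathway and 0.42 for hypoxia and glycolysis. Not past the threshold were cell cycle (0.29), Polycomb (0.29), erythroid (0.36), Schwann cell (0.42) and housekeeping (0.28) genes. The Wnt and Hedgehog call (adjusted p = 0.0396) was lost in 14 alternative settings and kept in 5. Leaving out 1 tumour also ended the call for endothelium (tumour 7, adjusted p = 0.0759), the p53 pathway (tumour 15, adjusted p = 0.0771) and hypoxia (tumours 8, 12 and 14, adjusted p = 0.0519, 0.224 and 0.0560). The calls for cartilage and hypoxia were lost with the mean of all probe sets (adjusted p = 0.0574 each), those for cartilage and skin epithelium without a filter (adjusted p = 0.174 and 0.0644), and that for hypoxia with a pseudocount of 1 (adjusted p = 0.0668). The p53 pathway call was lost with a pseudocount of 64 (adjusted p = 0.0593) and with brightness and the 3'/5' ratio of the control probe sets removed (adjusted p = 0.125). On the values as deposited 11 lists passed, without diagnostic and neural markers, the p53 pathway, hypoxia, Wnt and Hedgehog, skin epithelium, interferon response and endothelium.

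No single gene passed limma's variance test after adjustment (0 of 11931), and the smallest adjusted p was 0.580. In this test 668 genes had an unadjusted p under 0.05. The prior was fitted to the variances of these same genes, so a count near 596.55 is built in. The count therefore does not show whether genes vary between tumours. Adjusted over the list alone, 25 of 25 muscle genes, 5 of 10 fat cell genes, 5 of 12 skin epithelium genes, 2 of 28 macrophage genes and 4 of 4 sex-linked genes passed, against 0 over all genes. In the other 20 lists 0 genes passed either way. The test had almost no power on simulated data. Among usable skin epithelium genes, Epcam (SD 2.04) and Cdh1 (SD 1.63) varied most, and the keratinocyte genes Lor (SD 0.20) and Krt10 (SD 0.31) least. The calls for this list therefore do not show that skin content differed between tumours. In a test chosen after the data were seen, 2 probe sets of the same gene followed each other over tumours in 1388 of 4262 genes (permutation test, adjusted p under 0.05), and such agreement includes any technical difference that both probe sets share.

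**Figure D2:**
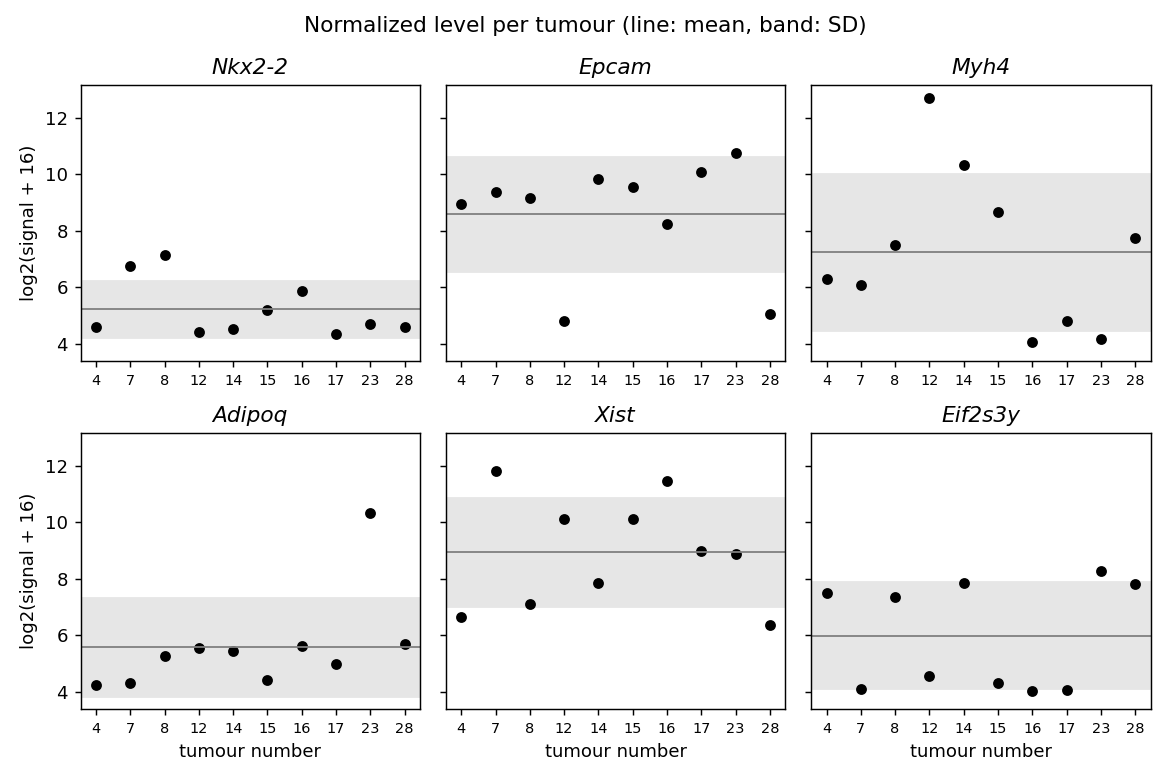
Quantile normalized log2(signal + 16) per tumour for 6 genes, with points for the 10 tumours, a line at the mean and a band of 1 SD on each side. Myh4, above background in 7 tumours, spans 8.65 log2 units with its highest value in tumour 12. The added 16 limits how low its values can be, so the span depends on it. Adipoq is highest in tumour 23 at 10.33, and Epcam is at 4.81 and 5.05 in tumours 12 and 28.

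Genes of several cell type lists moved together between tumours. The mean pairwise correlation over tumours was 0.848 among muscle genes, 0.729 among fat cell genes, 0.604 among fibroblast and matrix genes, 0.518 among macrophage genes, 0.505 among lymphocyte genes, 0.457 among interferon response genes and 0.376 among endothelial genes, each with an adjusted p of 0.000256, from an unadjusted p of 0.0001, the smallest the random lists can give. Without tumour 7 it was 0.252 for macrophage, 0.296 for interferon response and 0.224 for endothelial genes, and without tumour 23 it was 0.335 for fat cell genes, all still past the threshold. Cell cycle genes (0.214) and EWS-FLI1 repressed genes (0.324) also moved together (adjusted p = 0.000256), as did joint progenitor (0.174, adjusted p = 0.00161), p53 pathway (0.105, adjusted p = 0.0142), hypoxia (0.0919, adjusted p = 0.0176) and skin epithelium genes (0.146, adjusted p = 0.0242). The last 3 calls were lost without tumour 7 (p53 pathway, adjusted p = 0.0607), without tumour 4 (hypoxia, adjusted p = 0.0638) and without any of tumours 4, 8, 12, 16 and 23 (skin epithelium, adjusted p = 0.0627, 0.0548, 0.164, 0.0706 and 0.0860). All 3 were also lost with brightness and the 3'/5' ratio removed (adjusted p = 0.159, 0.0769 and 0.213, in the same order), and hypoxia with trimmed mean scaling (adjusted p = 0.107). Calls were gained for Polycomb and for Wnt and Hedgehog genes with the mean of all probe sets (adjusted p = 0.0334 and 0.0112), for Wnt and Hedgehog genes without tumour 23 (adjusted p = 0.0209), for diagnostic and neural markers with genes above background in all tumours (adjusted p = 0.0214), and for erythroid genes without tumour 28 (adjusted p = 0.0329) and without the 3 dimmest arrays (adjusted p = 0.0310). EWS-FLI1 activated genes were not past the threshold (0.0335, adjusted p = 0.0786). In all, 13 of 23 lists passed, against 2 on the values as deposited, where random lists also share the brightness of the array.

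**Figure D3:**
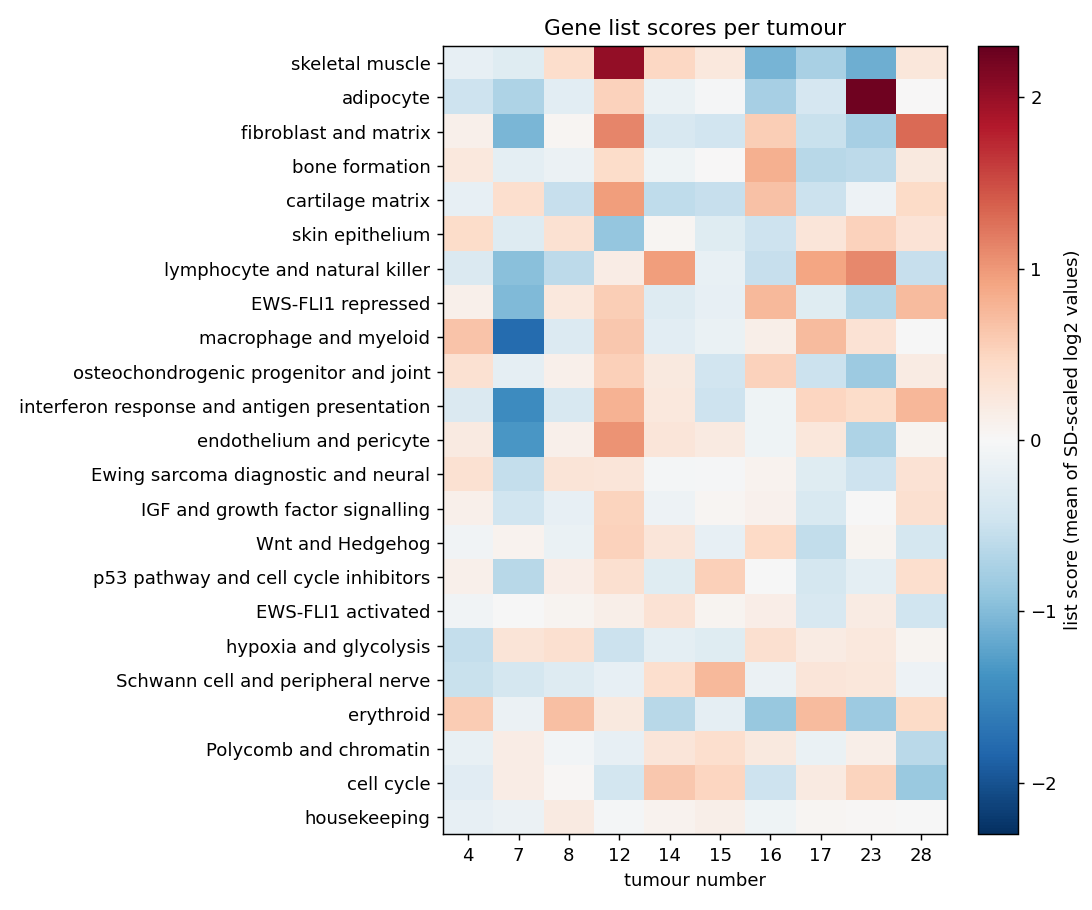
Scores of the 23 tested lists, from the largest median SD at the top to the smallest, in the 10 tumours, in units of SD-scaled log2 values, with red above and blue below the mean over tumours. The muscle score is 2.02 in tumour 12, the fat cell score 2.23 in tumour 23 and the macrophage score -1.78 in tumour 7.

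The design assumed that EWS-FLI1 activated and repressed genes, taken from human cells, would be opposed between tumours if the activity of the fusion differed. Nothing here measured that activity, so the comparison cannot decide whether it differed. No opposed relation was detected (r = -0.204, permutation p = 0.568, adjusted p = 0.815 over 229 pairs, rho = -0.176, permutation p = 0.632). Without tumours 17 and 28, the farthest from the median, r was 0.0393 (exact permutation p = 0.927), and without tumour 28 alone it was 0.0199. On the values as deposited the sign was opposite (r = 0.795, permutation p = 0.00537), and with the cell cycle score regressed out r was 0.375 (permutation p = 0.281).

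EWS-FLI1 repressed genes had high scores in tumours where fibroblast and matrix genes did (r = 0.885, permutation p = 0.00058, adjusted p = 0.118, rho = 0.915, permutation p = 0.00053, and r = 0.924 without tumours 7 and 16), with genes of both lists left out. Cell cycle scores ran against fibroblast and matrix scores (r = -0.867, permutation p = 0.00148, adjusted p = 0.118, rho = -0.782, permutation p = 0.0101, and r = -0.752 without tumours 16 and 28). After adjustment 0 of 229 pairs passed, although 37 had an unadjusted permutation p under 0.05 where chance gives 11.45. Without tumour 16 the first of these relations passed (r = 0.918, exact permutation, adjusted p = 0.0464). On the values as deposited 128 pairs passed and the second relation had the opposite sign (r = 0.513), and with genes above background in all tumours 5 pairs passed, both of these among them.

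Wnt and Hedgehog genes followed brightness (r = 0.897, permutation p = 0.00069, adjusted p = 0.0159 over 23 lists, rho = 0.867, permutation p = 0.00195, and r = 0.806 without the 2 farthest tumours). The erythroid score followed the 3'/5' ratio (r = 0.852, permutation p = 0.00197, adjusted p = 0.0453, rho = 0.818, permutation p = 0.00604, adjusted p = 0.0796, so rho did not pass), and without the 2 farthest tumours r was 0.659 (exact permutation p = 0.0780), not past the threshold with 8 tumours. It ran against brightness (r = -0.792, permutation p = 0.00740, adjusted p = 0.0851, rho = -0.842, permutation p = 0.00381, adjusted p = 0.0292, and r = -0.645 without the 2 farthest, exact permutation p = 0.0889). The EWS-FLI1 activated score had r = 0.734 with brightness (permutation p = 0.0156, adjusted p = 0.120, rho = 0.842, permutation p = 0.00356, adjusted p = 0.0292), and without the 2 farthest tumours r was 0.659 (exact permutation p = 0.0715), also not past it. The 3'/5' ratio itself ran against brightness (r = -0.872, permutation p = 0.00143, adjusted p = 0.00214, rho = -0.842, permutation p = 0.00382, and r = -0.824 without the 2 farthest). The first principal component held 27.6% of the variance and the next 21.9%. The first was related to brightness (r = -0.744, permutation p = 0.0148, adjusted p = 0.0148, rho = -0.770, permutation p = 0.0128), and without the 2 farthest tumours r was -0.612 (exact permutation p = 0.107), not past the threshold with 8 tumours. Correlations across genes between tumours ran from 0.859 to 0.973.

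Sex-linked genes differed between tumours. Xist, the RNA that coats the inactive X chromosome, was above background in 10 of 10 tumours (8.94 ± 1.94), from 6.36 in tumour 28 to 11.82 in tumour 7. The Y chromosome genes Eif2s3y (5.99 ± 1.89), Kdm5d (5.18 ± 0.99) and Uty (5.40 ± 1.30) were above background in 5 tumours each. Eif2s3y was at 7.49, 7.35, 7.86, 8.28 and 7.81 in tumours 4, 8, 14, 23 and 28, and at 4.10, 4.56, 4.31, 4.02 and 4.08 in tumours 7, 12, 15, 16 and 17. Of the mast cell genes, 1 of 11 was above background in all tumours, and among them Kit was at 6.38 ± 0.47.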

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

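Tests in this part were chosen after the results were seen, among them the reassignment of array measures, whose rule was written before its own result. Each of 182 values (list scores, array measures and named genes) was examined for a tumour standing apart from the other 9, and 9 did, where chance gives 9.1, so single entries carry little weight. The gap to the nearest tumour as a share of the whole range is given for each. It was 0.494 for the skeletal muscle score, with tumour 12 highest at 2.02 and the next at 0.467, and 0.565 for the muscle gene Pygm (8.05 in tumour 12, next 5.80). It was 0.566 for the fat cell score, with tumour 23 highest at 2.23, and 0.763 for Adipoq (10.33, next 5.68). It was 0.585 for the macrophage score, with tumour 7 lowest at -1.78, and 0.654 for the macrophage gene Cd68 (6.75, next 7.63). For Ighm, an antibody gene, it was 0.494 with tumour 14 highest at 8.78. For Krt5, chosen after its values were seen, it was 0.550 with tumour 23 highest at 5.90, and for Ramp2 it was 0.525 with tumour 28 lowest at 5.93.

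The spread of myofibre genes between tumours was weighed first. Brightness and RNA quality as the whole source are argued against, since with both removed the median SD was 1.30, above all matched random lists. Host muscle carried into some tumours may account for it, since the median pairwise r of these genes was 0.904 and 22 of 25 had a slope of 0.5 to 1.5 on the mean of the others. Muscle formation by tumour cells stays open too. In tumour 12, 6 of 9 genes of muscle formation and regeneration were above background, but so were 66.2% of all genes there. The count therefore decides nothing, and regenerating host muscle could give the same. No biological explanation from the design was tested, since it names no difference between tumours.

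Macrophage, interferon, endothelial, matrix and lymphocyte genes were all lowest in tumour 7. Array brightness is argued against as the whole source, since 4 of the 5 lists stayed lowest there with brightness and the 3'/5' ratio removed. A smaller share of host cells in tumour 7 stays open, since the 5 lists were picked as lowest there and their like deviations (mean -0.74, SD 0.19 over lists, a mean of 3.86 SDs) therefore decide nothing. EWS-FLI1 repressed (-0.63), diagnostic and neural (-0.43) and p53 pathway genes (-0.27) were lowest in tumour 7 too, as were mast cell genes (-0.60). The repressed list shares genes such as Col3a1 and Fn1 with the matrix list, so it is not free of host signal. With shared genes left out, matrix scores still went with repressed (r = 0.885) and diagnostic scores (r = 0.825), though neither passed after adjustment. These lists therefore do not argue against a smaller share of host cells. Muscle (-0.40) and fat cell genes (-0.26) lay below the median tumour in tumour 7 but were lower in other tumours. No biological explanation from the design was tested, since it names no difference between tumours.

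A set of 28 epithelial junction genes was assembled after Epcam, Esrp1 and Cdh1 had been seen, and of its 25 usable genes 8 were above background in tumour 12 and 3 in tumour 28, against 20 to 24 in each other tumour. Skin carried into the other tumours is argued against, since 2 of 14 keratinocyte genes were above background in at least 8 tumours, and so is array brightness alone, since 1 of tumours 12 and 28 lies among the 5 brightest arrays and the other among the 5 dimmest. Few tumour cells in tumours 12 and 28 stays open. Cell cycle genes lay at -0.12 and -0.39 from the median tumour where the epithelial genes were at -1.30 and -1.22. But by this median these were the 2 tumours lowest in cell cycle genes, and matrix genes were highest in the same tumours (0.91 and 1.06). Muscle (4.15) and endothelial genes (0.53) were highest in tumour 12. Fat cell (0.59), interferon response (0.38), macrophage (0.25) and lymphocyte genes (0.22) lay above the median tumour there, while skin epithelium (-0.24) and Schwann cell genes (-0.10) lay below it. In tumour 28 interferon response (0.48) and erythroid genes (0.66) were highest, but macrophage (-0.02), endothelial (-0.07) and lymphocyte genes (-0.14) were not raised. Removing brightness and the 3'/5' ratio together could not decide whether they gave the pattern. It left -0.28 in tumour 12 and -0.78 in tumour 28, although the 2 arrays lie at opposite ends in brightness. A test added because of that result found as small a deviation in a share of 0.0569 of 1000 random reassignments of both measures. Tumours 8 and 17 lay near tumour 28 in brightness (5.22 and 4.93 against 5.20) and in the log2 ratio (1.06 and 1.13 against 1.24). Their epithelial medians were 0.14 and 0.33 against -1.22. This goes against the 2 measures as the whole source in tumour 28, but it rests on 1 array and leaves tumour 12 open. No biological explanation from the design was tested, since it names no difference between tumours.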

How the results depend on the processing

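Trimmed mean scaling, removal of brightness and the 3'/5' ratio, leaving out the 3 dimmest arrays, leaving matrix genes out of the repressed list and the comparison of 2 probe sets were chosen after the results were seen; the other settings were planned. The values as deposited changed most results. There 11 lists varied more and 2 co-varied more than random lists, 128 pairs passed, the activated against repressed r was 0.795 and the first component held 64.6%. Mean pairwise r fell below that of random lists for activated (0.515), repressed (0.595), diagnostic (0.316), bone (0.480), p53 (0.563), hypoxia (0.598), IGF (0.519), skin (0.152), erythroid (0.252) and Schwann cell genes (0.440). Median SD changed sides of the random lists for hypoxia (0.62), Polycomb (0.69), erythroid (0.51) and housekeeping (0.56), and r changed sign for cell cycle with matrix (0.513) and with repressed genes (0.650). With the mean of all probe sets the diagnostic mean r was -0.0057 and the housekeeping median SD 0.18, then below random lists (adjusted p = 0.0360). A pseudocount of 1 gave a Polycomb median SD of 0.42 and a Schwann cell mean r of -0.0194. Without a filter the erythroid and housekeeping median SDs were 0.27 and 0.28. With genes above background in all tumours the Wnt and Hedgehog mean r was -0.0710, 5 pairs passed and the first component held 34.4%. Trimmed mean scaling gave a Polycomb median SD of 0.35. Removal of brightness and the 3'/5' ratio gave median SDs of 0.25 for Polycomb and 0.26 for erythroid and a Wnt and Hedgehog mean r of -0.0231. Without the 3 dimmest arrays the erythroid median SD was 0.26. Regressing out the cell cycle score gave an activated against repressed r of 0.375. With the 99th percentile as background 4728 genes were above it in all tumours. Agreement of 2 probe sets called 1388 genes, or 1381 with brightness and the ratio removed, where the variance test called 0 under each setting. Leaving out each tumour gave from -0.347 to 0.0199 for activated against repressed, 27.6% to 32.3% for the first component, 0 to 1 pairs, 16 to 17 lists for variation, 11 to 14 lists for co-variation, -0.0624 to 0.189 for the Schwann cell mean r, and median SDs of 0.26 to 0.32 for Polycomb, 0.25 to 0.30 for cell cycle, 0.34 to 0.37 for erythroid and 0.23 to 0.30 for housekeeping. The cause of these changes was not tested, though the values as deposited carry the brightness of each array. Over the other list results 386 values of mean r and 376 of median SD kept their side and their call, 18 and 31 lost the call, and 6 values of mean r gained it. For the SDs of single genes, named genes and those of largest SD, 2133 values moved by less than a jackknife standard error and 323 by at least that. Signal over background limits dim arrays, where fewer genes were above background.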

Other observations

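The genes and the epithelial gene set in this part were chosen after their values were seen, apart from members of the fixed lists taken by the rule for named genes. Epcam, an epithelial adhesion gene, was at 8.24 to 10.77 in 8 tumours and at 4.81 and 5.05 in tumours 12 and 28. In tumours 12 and 28 the splicing regulator gene Esrp1 (7.54 ± 1.80, SD, n = 10) was at 4.34 and 4.11, Ap1m2 (7.20 ± 1.48) at 4.12 and 4.78, the tight junction gene Cldn6 (6.79 ± 1.33) at 4.15 and 4.59, and the protease gene St14 (6.62 ± 1.24) at 4.79 and 4.15. Of the skin genes, Krt10 was above background in 10 tumours, Lor in 9, Krt5 in 4, Krt14 in 1, and Krt1 and Krt17 in 0. The keratin genes Krt8 and Krt18 were highest in tumour 23, at 8.83 and 7.84.

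Rspo3, which encodes an enhancer of Wnt signalling, spanned 4.90 log2 units and was at 9.72 in tumour 16 and 4.81 in tumour 17. The homeobox gene Lhx8 (5.94 ± 1.96) was at 9.28 in tumour 4 and 4.06 in tumour 28. The acute phase gene Saa3 (7.27 ± 1.99) was at 11.84 in tumour 4, the tumour in which S100a8 was also highest, and at 5.14 in tumour 7. The B cell gene Ms4a1 was at 7.25 in tumour 23 and 6.07 in tumour 14.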
